A study of Mus musculus with 6 samples.

How the data were processed

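Gene expression was measured by RNA sequencing in 6 libraries of mouse pancreatic tumour cells (KPCY cells), 2 for each of 3 short hairpin RNAs: a non-targeting control (shNT) and hairpins 1 and 2 against Pthlh, the gene of parathyroid hormone-related protein. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, RNA was extracted with Qiagen RNeasy and libraries were made by Novogene. The series design speaks of 2 parental clones, and no label ties a library or a hairpin to a clone. The labels give the condition as tumour cells sorted after growth in mice, while the labels' protocols describe culture in DMEM and transduction, so which of these preceded RNA extraction is not settled. Nothing in the labels says that replicates came from separate cultures or animals, so the p-values measure only the spread between these libraries, which may be technical.

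The authors deposited a table of TPM, transcript abundances scaled to a total of 1000000 per library, for 24493 genes. Per the submitters' processing notes, Salmon, R 3.5 and DESeq2 were used with the mm10 build; the notes give no version of Salmon and do not say what DESeq2 was used for. TPM keeps no trace of the number of reads, so the depth of each library is unknown and no counting interval or floor is given. Genes listed at 0 in both libraries of a group were given no fold.

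TPM values were used as deposited, without further scaling. Genes with a TPM of at least 1 in at least 2 libraries were kept, which left 11549. Values were tested on the log2(TPM + 1) scale with limma 3.58.1 in R 4.3.3. The model held 3 group means over all 6 libraries, with a variance prior that followed mean expression, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. This scale understates the change of genes with low TPM. The knockdown comparison was the mean of the 2 hairpin group means minus shNT. Each hairpin was also compared with shNT, and hairpin 2 with hairpin 1. Pthlh lay below the expression filter, so its test came from the same model fitted without the filter, which departs from the planned filter.

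The test, the gene lists, the rule for named genes and the first set of alternatives were chosen before the data were examined. Of 19 gene lists, the 18 reported covered PTHrP and cAMP signalling, epithelial junctions, mesenchymal genes, TGF-beta response, RAS-MAPK output, S phase, G2-M phase, p53 targets and senescence, interferon response, chemokines, cachexia-associated factors, hypoxia and glycolysis, unfolded protein response, cholesterol synthesis, YAP-TEAD targets, classical and basal-like tumour subtypes, and mitochondrial transcripts. The 8 lists of markers of other cell types covered myeloid cells, neutrophils, lymphocytes, fibroblasts, endothelium, acinar cells, islets and erythroid cells. Ctgf, Axl and Inhba, among others, are in more than 1 list. Lists were tested against the other genes with camera in limma at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation. The minimum of 3 tested members for a list test, met by 20 lists, was set after the design was fixed.

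The named genes were Pthlh, then the 10 largest rises and 10 largest falls in the knockdown comparison. These had an adjusted p below the threshold, a mean TPM of at least 2, both hairpin means on the same side of shNT and a symbol that is not a predicted gene or clone name. The rule also took up to 4 members of each list with the smallest p, and the 5 largest differences between hairpins in each direction. Of the members it took from a list, only some are printed with their values, and that choice was made after the values were seen. Gene positions came from the GENCODE M21 annotation of the same build, which placed 98.8% of tested genes. Prl2c3 and Prl2c4 belong to a family of near-identical genes, and Ugt1a7c shares its last exons with the other Ugt1a genes, so their values are uncertain. Entries named Mir are short precursor entries whose TPM is divided by a very short length.

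The model was tested on simulated data before use. For the knockdown comparison over 11549 genes, 82% of genes given a change of 0.5 were recovered, 96% at 1 and 100% at 2 and 3 (log2), while 8 of 11349 unchanged genes were called. The list test called 1 of 1 shifted list and 0 of 19 unshifted lists. The changed genes were drawn from those above a minimum mean expression, and both hairpins were given the same change. The simulated noise was independent between genes. These simulations therefore do not cover genes of low expression, differences between hairpins or correlation between genes. Alternatives covered the pseudocount, the filter, quantile and median-ratio scaling, the variance prior, a replicate block, fits of the compared groups alone and the omission of each library. Removal of trends with transcript length or GC content, centring of each chromosome, omission of small-RNA entries and separate controls for each hairpin were added after seeing the data. Genes without a symbol in the table, isoforms and sequence variants were not analysed here.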

Results

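RNA was sequenced from 6 libraries of KPCY cells, tumour cells from a mouse model of pancreatic cancer with a yellow fluorescent lineage label. The cells carried a non-targeting hairpin (shNT, n = 2), Pthlh hairpin 1 (n = 2) or Pthlh hairpin 2 (n = 2). The depth of the libraries is unknown. Replicates correlated across genes at r = 0.987 for shNT, 0.992 for hairpin 1 and 0.991 for hairpin 2 on the log2(TPM + 1) scale. Between groups, r was 0.960 to 0.965 for shNT and hairpin 1, 0.982 to 0.988 for shNT and hairpin 2, and 0.969 to 0.970 for the hairpins; genes are not independent replicates. The Mir6236 entry took 34.1% and 24.3% of all TPM in the shNT libraries, 20.4% and 19.7% with hairpin 1, and 23.4% and 21.4% with hairpin 2.

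The first comparison asked whether the targeted gene was lowered. Pthlh (chromosome 6, 147252101 to 147264183, minus strand, mm10) encodes parathyroid hormone-related protein, a secreted ligand of the receptor Pth1r. Its level was 0.859 ± 0.152 TPM (SD, n = 2) in shNT, with 0.752 and 0.966 in the separate libraries. It was 0 and 0.106 TPM with hairpin 1, and 0.0423 and 0.263 TPM with hairpin 2. The means with hairpins 1 and 2 were 6.14% and 17.8% of the shNT mean.

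Pthlh fell by 0.76 ± 0.10 (log2, SE) in the knockdown comparison, limma adjusted p = 0.0120 without the expression filter, and was lower in 4 of 4 knockdown libraries than in either shNT library. Against shNT the change was -0.82 with hairpin 1 (limma adjusted p = 0.00837) and -0.69 with hairpin 2 (limma adjusted p = 0.0583), which missed the threshold. The hairpins differed by 0.13 (95% interval -0.18 to 0.44; limma adjusted p = 0.533). An exact one-sided permutation test of the 4 knockdown against the 2 shNT libraries gave p = 0.0667, the smallest that 15 splits allow. The knockdown call was lost without shNT replicate 1 (limma adjusted p = 0.0575), shNT replicate 2 (0.0666), hairpin 1 replicate 1 (0.0729), hairpin 1 replicate 2 (0.0656) or hairpin 2 replicate 1 (0.0513). The Pthlh change was -2.40 with a pseudocount of 0.1 and -1.19 with 0.5, so its size rests on the pseudocount. Over 17 alternatives the limma adjusted p ranged from 0.00714 to 0.0980. The highest Pth1r level in any library was 0.105 TPM and the highest Pth2r level 0.0613 TPM.

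**Figure D1:**
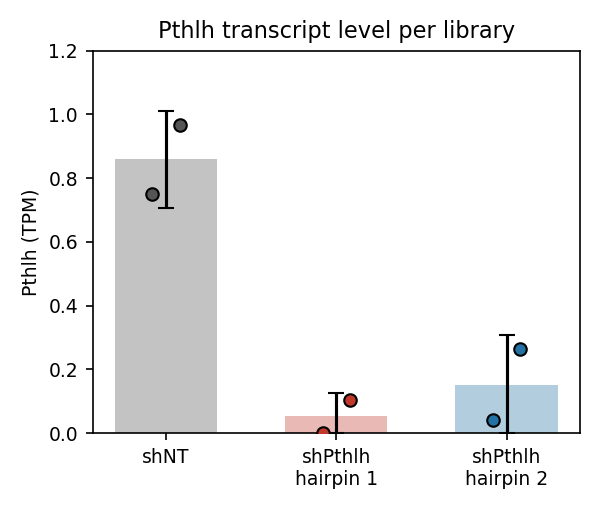
Pthlh level in TPM (vertical axis) in the shNT, hairpin 1 and hairpin 2 groups; bars are means of 2 libraries, points are libraries and error bars are SD, drawn down to 0 at most. The shNT libraries were at 0.752 and 0.966 TPM and the highest knockdown library at 0.263.

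The main comparison set the mean of both hairpins against shNT. Genes of cholesterol synthesis fell with each hairpin, 13 of 18 YAP-TEAD targets fell, and 19 of 26 genes of hypoxia and glycolysis rose. Cdx2, an intestinal transcription factor, went from 0.229 ± 0.146 TPM in shNT to 47.8 ± 0.0644 with hairpin 1 and 1.01 ± 0.0551 with hairpin 2 (SD, n = 2). Sulf2, a heparan sulfate endosulfatase, went from 14.5 ± 0.844 to 0.793 ± 0.142 and 3.82 ± 0.508 TPM. Of 11549 genes tested with limma, 4550 passed, 3149 higher and 1401 lower.

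Those counts depended on scale and on the spread between hairpins. The median of all genes was shifted by 0.10 (log2) in deposited TPM and by 0.01 after median-ratio scaling, where 1742 genes were higher and 2155 lower; without small-RNA entries 963 were higher and 1944 lower. The count was 2777 without hairpin 1 replicate 1, 2792 without hairpin 1 replicate 2, 2850 without hairpin 2 replicate 1 and 2727 without hairpin 2 replicate 2. With both hairpins pooled as 1 group of 4, so that the difference between hairpins entered the spread, limma called 1 gene, and 2567 genes had an unadjusted p under 0.05. That gene was the integrin Itga2, named after its values were seen (39.0 TPM in shNT, 19.4 and 19.5 with hairpins 1 and 2; limma adjusted p = 0.0302).

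Among the largest rises, Cdx2 (chromosome 5, 147300805 to 147307270) rose by 3.02 ± 0.09 (log2, SE; limma adjusted p = 0.000136). Tff2, a secreted trefoil peptide of gastric mucosa, rose by 2.42 ± 0.20, from 2.63 TPM to 28.4 and 12.3 with hairpins 1 and 2. Igfbp5, an insulin-like growth factor binding protein, rose by 2.37 ± 0.09 through hairpin 1 (44.2 TPM, against 0.959 in shNT); hairpin 2, at 1.27 TPM, missed the threshold (limma adjusted p = 0.216). Ugt1a7c, a glucuronosyltransferase, rose by 2.48 ± 0.05, and the placental prolactin family entries Prl2c3 and Prl2c4 rose by 2.71 ± 0.07 and 2.63 ± 0.48. Prl2c4 was at 0 and 2.59 TPM in the shNT libraries and missed the threshold with hairpin 2 (limma adjusted p = 0.0829). Reads of these 3 are shared with near-identical sequence, so their values are uncertain. The precursor entries Mir23a and Mir421 rose and were listed at 0 in both shNT libraries.

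The remaining rises, Rnu11 by 2.56 ± 0.78 and Mir467g by 2.36 ± 0.64 (log2, SE), rested on few libraries. Neither passed with hairpin 1 (limma adjusted p = 0.129 and 0.0626) or with hairpin 2 (limma adjusted p = 0.0776 and 0.0770). The Rnu11 call was lost after median-ratio scaling (limma adjusted p = 0.0592) and without hairpin 1 replicate 1 (0.124), hairpin 1 replicate 2 (0.102), hairpin 2 replicate 1 (0.115) or hairpin 2 replicate 2 (0.107). Over its alternatives the Rnu11 adjusted p ranged from 0.000494 to 0.179. The Mir467g call was lost without shNT replicate 1 (limma adjusted p = 0.121), hairpin 1 replicate 1 (0.0641), hairpin 1 replicate 2 (0.0961) or hairpin 2 replicate 1 (0.0765).

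Among the largest falls, Sulf2 (chromosome 2, 166073089 to 166155663) fell by 2.40 ± 0.09 (log2, SE; limma adjusted p = 0.000251). Thbs1 (chromosome 2, 118111876 to 118127133), the matricellular protein thrombospondin 1, fell by 2.25 ± 0.06, from 19.2 TPM to 0.853 and 8.66. Mmp13, a collagenase, fell by 1.99 ± 0.10, and Timp3, an inhibitor of such proteases, fell by 1.73 ± 0.05. The actin-binding Dbn1 fell by 1.99 ± 0.07, the integrin-binding Fermt2 fell by 1.79 ± 0.06 and the heparan sulfate sulfotransferase Hs6st2 fell by 1.64 ± 0.06. Of the precursor entries, Mir7669 fell and was listed at 0 with hairpin 2, and Mir1b fell and was listed at 0 with hairpin 1, without a call for hairpin 2 (limma adjusted p = 0.200). Mir1956 fell and was listed at 0 with hairpin 2, without a call for hairpin 1 (limma adjusted p = 0.265); its call was lost without shNT replicate 2 (limma adjusted p = 0.0532), hairpin 2 replicate 1 (0.0540) or hairpin 2 replicate 2 (0.0555).

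Cholesterol synthesis genes fell with both hairpins. Of 23 tested members, 22 fell in the knockdown comparison and 0 rose; 23 fell when adjusted over the list alone, and 23 after median-ratio scaling. Idi1, an isoprenoid isomerase, went from 178 ± 1.40 TPM in shNT to 71.9 ± 0.361 and 101 ± 2.26 with hairpins 1 and 2 (SD, n = 2), and fell by 1.06 ± 0.04 (log2, SE). Msmo1, Cyp51 and Fdps, enzymes of the same pathway, fell by 0.88 ± 0.04, fell by 0.84 ± 0.04 and fell by 0.84 ± 0.04. The median change of the list was -0.75, against 0.10 for all genes. Srebf2, a transcription factor that drives these genes, was the member that did not pass (-0.16, limma adjusted p = 0.0911). The list differed from other genes by camera in limma (adjusted p = 1.57e-22, and adjusted p = 0.0310 with an estimated correlation). With the hairpins pooled as 1 group limma called 0 of the 23, and 22 had an unadjusted p under 0.05.

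YAP-TEAD targets fell mainly through hairpin 1. Of 18 tested members 13 fell and 0 rose, 13 when adjusted over the list alone and 15 after median-ratio scaling. Cyr61 and Ankrd1, often used as readouts of YAP activity, fell by 1.39 ± 0.06 and fell by 1.03 ± 0.04 (log2, SE). F3, tissue factor, fell by 0.59 ± 0.03, and Amotl2, an angiomotin, fell by 0.71 ± 0.05, without a call for hairpin 2 (limma adjusted p = 0.870). Camera in limma gave adjusted p = 5.06e-11, and adjusted p = 0.133 with an estimated correlation. With hairpin 2, Cyr61 was at 104 TPM against 101 in shNT (0.04, limma adjusted p = 0.737) and 13.5 with hairpin 1. Ankrd1 lies on chromosome 19 and Amotl2 on chromosome 9, where the median gene was at -0.17 and -0.24 with hairpin 1 relative to all genes. After chromosome centring 17 of 18 members fell in the knockdown comparison and 17 with hairpin 1. Camera in limma at the preset correlation then gave adjusted p = 1.14e-09 for the knockdown comparison.

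Genes of hypoxia and glycolysis rose. Of 26 tested members 19 rose and 1 fell, also when adjusted over the list alone, and 16 rose and 2 fell after median-ratio scaling. The member that fell was Pfkfb3 (-0.47), a regulator of glycolysis, named after its values were seen and not called for hairpin 2 (limma adjusted p = 0.557). Without shNT replicate 1, 2 members fell. Pfkl and Pfkp, phosphofructokinases, rose by 0.73 ± 0.04 and 1.44 ± 0.08 (log2, SE), Pfkp without a call for hairpin 2 (limma adjusted p = 0.0565). Hk1, a hexokinase, rose by 0.53 ± 0.03 and Pdk1, a kinase of pyruvate dehydrogenase, by 0.61 ± 0.06. Camera in limma gave adjusted p = 0.000600, and adjusted p = 0.333 with an estimated correlation.

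In RAS-MAPK output 9 of 21 tested members fell and 2 rose (11 and 3 when adjusted over the list alone). Dusp5, an ERK phosphatase, fell by 0.66 ± 0.04, Epha4, a receptor kinase, fell by 0.71 ± 0.06 and Hbegf, a growth factor, fell by 0.48 ± 0.04 (log2, SE). These 3 missed the threshold with hairpin 2 (limma adjusted p = 0.363, 0.515 and 0.208), where Dusp5 was above shNT. Spry1, an inhibitor of this pathway, rose by 0.49 ± 0.04, and Phlda1, named after its values were seen, by 0.33, the latter not called for hairpin 2 (limma adjusted p = 0.0746). Without shNT replicate 2, 4 members rose. Camera in limma gave adjusted p = 0.00154, and adjusted p = 0.192 with an estimated correlation.

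In the TGF-beta response 7 of 18 tested members fell and 3 rose, also when adjusted over the list alone. Pmepa1 and Skil, feedback inhibitors of this pathway, fell by 0.74 ± 0.04 and fell by 0.52 ± 0.04 (log2, SE). Id3 and Id2, inhibitors of helix-loop-helix factors, rose by 0.83 ± 0.05 and 0.61 ± 0.04, and Nedd9, named after its values were seen, by 0.37, without a call for hairpin 2 (limma adjusted p = 0.142). The Nedd9 call was lost without shNT replicate 2 (limma adjusted p = 0.0555), hairpin 1 replicate 1 (0.0532), hairpin 1 replicate 2 (0.0660), hairpin 2 replicate 1 (0.0614) or hairpin 2 replicate 2 (0.0609). Camera in limma gave adjusted p = 0.00431, and adjusted p = 0.192 with an estimated correlation.

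Among mesenchymal genes 7 of 16 tested members fell and 4 rose, 8 and 4 when adjusted over the list alone. Thbs1 fell by 2.25 ± 0.06 and Cald1, an actin regulator, fell by 0.44 ± 0.04 (log2, SE). Sparc, a matricellular protein, fell by 0.53 ± 0.05, without a call for hairpin 2 (limma adjusted p = 0.244), where it was above shNT. Twist2, a mesenchymal transcription factor, rose by 1.43 ± 0.17, with 0.595 TPM in shNT, 15.2 under hairpin 1 and 0.0878 under hairpin 2 (limma adjusted p = 0.142). The other rises, named after their values were seen, were S100a4 (1.26), Loxl2 (0.29) and Tpm2 (0.25), none of them called for hairpin 2 (limma adjusted p = 0.349, 0.147 and 0.764). The number that fell was 4 without hairpin 1 replicate 1, hairpin 1 replicate 2, hairpin 2 replicate 1 or hairpin 2 replicate 2. Camera in limma gave adjusted p = 0.00568, and adjusted p = 0.333 with an estimated correlation.

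In the list of PTHrP and cAMP signalling, 3 of 13 tested members fell and 1 rose, also when adjusted over the list alone, and 5 fell and 1 rose after median-ratio scaling. After chromosome centring 5 fell and limma called 0 higher, with 1 higher at unadjusted p under 0.05. Mmp13 and Stc1, a secreted glycoprotein, fell by 1.99 ± 0.10 and fell by 0.78 ± 0.09 (log2, SE). Dusp1, a phosphatase, fell by 0.29 ± 0.07, a call lost without shNT replicate 2 (limma adjusted p = 0.0889), hairpin 1 replicate 2 (0.0639), hairpin 2 replicate 1 (0.0756) or hairpin 2 replicate 2 (0.0762). Per1, a clock gene, rose by 0.36 ± 0.08, a call lost without shNT replicate 1 (limma adjusted p = 0.0794), hairpin 1 replicate 1 (0.0572), hairpin 2 replicate 1 (0.0672) or hairpin 2 replicate 2 (0.0501). Neither passed with hairpin 2 (limma adjusted p = 0.129 and 0.107), where Dusp1 was higher than in shNT (0.23). Camera in limma gave adjusted p = 0.0250 for PTHrP and cAMP-PKA-CREB signalling, but 0.115 without shNT replicate 1 and 0.0547 with a mean TPM of at least 5, in a range of 0.00154 to 0.289 over its alternatives. It was lost at adjusted p = 0.289 with an estimated correlation.

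S phase genes rose in deposited TPM, 16 of 30 tested members with 0 falling (16 and 1 when adjusted over the list alone). Mcm7, a replicative helicase subunit, rose by 0.40 ± 0.04 and Rrm2, a ribonucleotide reductase subunit, by 0.39 ± 0.04 (log2, SE). After median-ratio scaling 11 rose and 3 fell, after chromosome centring 11 rose and 1 fell, and the camera result of limma moved from adjusted p = 0.0135 to 0.0736. For S phase it was 0.0885 after quantile normalization and 0.231 without small-RNA entries, in a range of 0.000592 to 0.317 over its alternatives, and adjusted p = 0.317 with an estimated correlation.

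In G2-M phase 8 of 30 tested members rose and 5 fell, also when adjusted over the list alone, and 4 rose and 8 fell after median-ratio scaling. After chromosome centring only 1 rose and 2 fell, so most of these calls were lost. The number that rose was 5 without hairpin 1 replicate 2, hairpin 2 replicate 1 or hairpin 2 replicate 2. Aurkb, a mitotic kinase, rose by 0.36 ± 0.04 and Kif23, a kinesin of cytokinesis, fell by 0.47 ± 0.06 (log2, SE), without a call for hairpin 2 (limma adjusted p = 0.0643). Ccnb2 (-0.36) also fell, as did Bub1b (-0.28), Tpx2 (-0.26) and Anln (-0.24), the last 3 named after their values were seen. These 3 missed the threshold with hairpin 2 (limma adjusted p = 0.396, 0.948 and 0.530), where Tpx2 and Anln were at 0.01 and 0.05. The Tpx2 call was lost without hairpin 1 replicate 1 (limma adjusted p = 0.0703), hairpin 1 replicate 2 (0.0548), hairpin 2 replicate 1 (0.0627) or hairpin 2 replicate 2 (0.0685). The list median was 0.06 in deposited TPM and -0.04 after median-ratio scaling, while camera in limma gave a lower direction without a call (adjusted p = 0.818).

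In the classical tumour subtype 11 of 23 tested members rose and 3 fell (12 and 3 when adjusted over the list alone), without a call by camera in limma (adjusted p = 0.330). Lgals4, an intestinal galectin, rose by 1.96 ± 0.04 and Foxa1, a pioneer factor, by 1.34 ± 0.09 (log2, SE), and the protease Ctse fell from 120 TPM to 43.0 and 71.6 with hairpins 1 and 2. Hnf4a (-0.17) and Foxa2 (-0.16) also fell through hairpin 1, without calls for hairpin 2 (limma adjusted p = 0.163 and 0.917), and were named after their values were seen; 1 member fell without hairpin 1 replicate 1, hairpin 1 replicate 2, hairpin 2 replicate 1 or hairpin 2 replicate 2. The Hnf4a call was lost without hairpin 1 replicate 1 (limma adjusted p = 0.0577), hairpin 1 replicate 2 (0.0672), hairpin 2 replicate 1 (0.0624) or hairpin 2 replicate 2 (0.0696). The Foxa2 call was lost without shNT replicate 1 (limma adjusted p = 0.0503), shNT replicate 2 (0.0870), hairpin 1 replicate 1 (0.110), hairpin 1 replicate 2 (0.0765), hairpin 2 replicate 1 (0.106) or hairpin 2 replicate 2 (0.0621). In the basal-like subtype 1 of 11 tested members rose and 3 fell, also when adjusted over the list alone, without a call by camera in limma (adjusted p = 0.133). After median-ratio scaling 1 rose and 4 fell, and with the length trend removed limma called 0 higher and 5 lower. Lamb3, an adhesion protein, fell by 0.70 ± 0.06 (log2, SE), Scel fell by 0.18 ± 0.04 and Sprr1b rose by 0.45 ± 0.11. All 3 were without a call for hairpin 2 (limma adjusted p = 0.0989, 0.136 and 0.432), where Scel was above shNT. The Sprr1b call was lost without shNT replicate 1 (limma adjusted p = 0.0992), hairpin 1 replicate 1 (0.0686), hairpin 1 replicate 2 (0.0714), hairpin 2 replicate 1 (0.0583) or hairpin 2 replicate 2 (0.0723). The Scel call was lost without shNT replicate 2 (limma adjusted p = 0.0501), hairpin 1 replicate 2 (0.0616), hairpin 2 replicate 1 (0.0656) or hairpin 2 replicate 2 (0.0683). The median of that list was 0.03, its mean -0.04 and the camera direction lower.

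Among epithelial junction genes 9 of 19 tested members rose and 6 fell, also when adjusted over the list alone, without a call by camera in limma (adjusted p = 0.991). The keratin Krt19 rose by 0.62 ± 0.05 and the transcription factor Elf3 by 0.53 ± 0.04 (log2, SE), both without a call for hairpin 2 (limma adjusted p = 0.691 and 0.520). Crb3, a polarity protein, rose by 0.54 ± 0.05. P-cadherin Cdh3 fell by 1.16 ± 0.08, without a call for hairpin 2 (limma adjusted p = 0.572), where it was above shNT. The number that fell was 2 without hairpin 1 replicate 1, hairpin 1 replicate 2, hairpin 2 replicate 1 or hairpin 2 replicate 2. The list median was 0.07 in deposited TPM and -0.03 after median-ratio scaling, and the camera direction was lower.

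Among chemokines 5 of 13 tested members rose and 2 fell (5 and 3 when adjusted over the list alone), without a call by camera in limma (adjusted p = 0.991). The neutrophil attractants Cxcl5, Cxcl3 and Cxcl2 rose by 1.18 ± 0.11, 1.29 ± 0.13 and 1.60 ± 0.17 (log2, SE). Ptgs2, a prostaglandin synthase, fell by 0.65 ± 0.07 without a call for hairpin 2 (limma adjusted p = 0.0955), where it was above shNT. The others, named after their values were seen, were Ccl2 (0.62, not called for hairpin 2, limma adjusted p = 0.213), Csf1 (0.38) and Cxcl16 (-0.59).

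In the list of cachexia-associated factors 2 of 7 tested members rose and 3 fell (3 and 3 when adjusted over the list alone), without a call by camera in limma (adjusted p = 0.542). Inhba, an activin subunit, fell by 0.68 ± 0.12, Gdf11 fell by 0.40 ± 0.09 and Tnfsf12 rose by 0.46 ± 0.08 (log2, SE). Lif, named after its values were seen, fell by 0.24 ± 0.07. Hairpin 2 gave no call for Inhba, Gdf11, Tnfsf12 or Lif (limma adjusted p = 0.256, 0.980, 0.194 and 0.194), with Gdf11 at 0.01 and Lif at 0.18. The Lif call was lost without shNT replicate 1 (limma adjusted p = 0.174), shNT replicate 2 (0.0625), hairpin 1 replicate 1 (0.0820), hairpin 1 replicate 2 (0.0937), hairpin 2 replicate 1 (0.0933) or hairpin 2 replicate 2 (0.107). The Gdf11 call was lost without shNT replicate 1 (limma adjusted p = 0.0929), shNT replicate 2 (0.0525), hairpin 1 replicate 1 (0.0538), hairpin 1 replicate 2 (0.0520), hairpin 2 replicate 1 (0.0617) or hairpin 2 replicate 2 (0.0517). Lcn2, a siderophore-binding protein, rose by 1.47 ± 0.30, a call lost without shNT replicate 1 (limma adjusted p = 0.0532) or hairpin 2 replicate 2 (0.05004). For hairpin 2 alone Lcn2 did not pass (limma adjusted p = 0.0561). The list median was -0.02, its mean 0.14 and the camera direction lower.

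Of 13 tested interferon genes 5 rose and 1 fell (6 and 1 when adjusted over the list alone), without a call by camera in limma (adjusted p = 0.341). After chromosome centring 4 rose and limma called 0 lower, with 1 lower at unadjusted p under 0.05. H2-D1, a class I antigen, and Oasl1 rose by 0.57 ± 0.04 and 0.70 ± 0.06 (log2, SE), as did Ifit2 (0.60). Bst2 (0.52) and B2m (-0.26) were named after their values were seen. Of these Oasl1, Bst2 and B2m were not called for hairpin 2 (limma adjusted p = 0.0840, 0.138 and 0.149). The Bst2 call was lost without hairpin 1 replicate 1 (limma adjusted p = 0.0534), hairpin 1 replicate 2 (0.0687), hairpin 2 replicate 1 (0.0614) or hairpin 2 replicate 2 (0.0646). The B2m call was lost without hairpin 1 replicate 2 (limma adjusted p = 0.0610), hairpin 2 replicate 1 (0.0578) or hairpin 2 replicate 2 (0.0610). Of 19 tested p53 and senescence genes 4 rose and 6 fell (6 and 6 when adjusted over the list alone; 2 and 8 after median-ratio scaling, 1 and 8 after chromosome centring), without a call by camera in limma (adjusted p = 0.0619). Igfbp3 fell by 1.61 ± 0.08 and Plk2 fell by 0.99 ± 0.07. Cdkn2b fell by 0.90 ± 0.07 and Cdkn2a fell by 0.70 ± 0.07. All 4 were without a call for hairpin 2 (limma adjusted p = 0.111, 0.375, 0.150 and 0.159). Plk2 and Cdkn2a were above shNT with hairpin 2, so their falls came from hairpin 1. The rises, named after their values were seen, were Bax (0.41), Btg2 (0.29), Phlda3 (0.27) and Zmat3 (0.22), also without calls for hairpin 2 (limma adjusted p = 0.0577, 0.942, 0.383 and 0.0774). The Btg2 call was lost without shNT replicate 1 (limma adjusted p = 0.169), hairpin 1 replicate 1 (0.107), hairpin 1 replicate 2 (0.0842), hairpin 2 replicate 1 (0.0724) or hairpin 2 replicate 2 (0.106). The Zmat3 call was lost without shNT replicate 1 (limma adjusted p = 0.0648), hairpin 1 replicate 1 (0.0514), hairpin 1 replicate 2 (0.0629), hairpin 2 replicate 1 (0.0600) or hairpin 2 replicate 2 (0.0654). That list had a median of 0.00 and a mean of -0.18.

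In the unfolded protein list 6 of 24 tested members rose and 3 fell, also when adjusted over the list alone, without a call by camera in limma (adjusted p = 0.639). With the length trend removed 3 rose and 3 fell. The chaperone Hspa5 fell by 0.46 ± 0.04 and Atf3 fell by 0.73 ± 0.08 (log2, SE), as did Phgdh (-0.18), named after its values were seen. All 3 missed the threshold with hairpin 2 (limma adjusted p = 0.0601, 0.0805 and 0.835), where Phgdh was at 0.02. The Phgdh call was lost without shNT replicate 1 (limma adjusted p = 0.0756), hairpin 1 replicate 1 (0.145), hairpin 1 replicate 2 (0.102), hairpin 2 replicate 1 (0.139) or hairpin 2 replicate 2 (0.103). Without shNT replicate 2, 10 members rose. Xbp1, a transcription factor of this response, rose by 0.42 ± 0.05, without a call for hairpin 2 (limma adjusted p = 0.661), where it was below shNT. Of 15 mitochondrial transcripts 0 were in the table under these names, so they were not analysed here.

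Markers of other cell types were low. The median marker of each of the 8 lists was at most 0.102 TPM in each group. Cd14, a myeloid marker, was at 67.9 TPM in shNT, 75.7 with hairpin 1 and 60.1 with hairpin 2 and was not called (-0.01, limma adjusted p = 0.861). The myeloid markers Mrc1 and Apoe rose by 0.86 ± 0.05 and 0.81 ± 0.11 (log2, SE), so 2 of 4 tested members rose and 0 fell, also when adjusted over the list alone (camera in limma, adjusted p = 0.388). Mrc1 was not called for hairpin 2 (limma adjusted p = 0.0551). The collagen Col5a1, the tested fibroblast marker, fell by 1.47 ± 0.08, from 4.43 TPM to 0.351 and 1.85, also when adjusted over the list alone. Of 3 tested acinar markers the elastase Cela1 fell by 0.43 ± 0.12, also when adjusted over the list alone (camera in limma, adjusted p = 0.639, lower, with a median of 0.16). Cela1 passed with neither hairpin alone (limma adjusted p = 0.102 and 0.0713). The Cela1 call was lost without shNT replicate 2 (limma adjusted p = 0.0658), hairpin 1 replicate 1 (0.111), hairpin 1 replicate 2 (0.0855), hairpin 2 replicate 1 (0.0837) or hairpin 2 replicate 2 (0.108). Of the 1 neutrophil, 1 lymphocyte, 2 endothelial and 1 erythroid markers tested, limma called 0 in the knockdown comparison, also when adjusted over the list alone, and 1, the endothelial Flt1, had an unadjusted p under 0.05 (0.0417). Of 10 islet markers 0 were tested.

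Each hairpin was then compared with shNT to see whether both gave the same changes. Hairpin 1 changed 5798 genes in limma, 3702 higher and 2096 lower, and hairpin 2 changed 1112, 765 higher and 347 lower. After median-ratio scaling these were 2623 and 2802, and 244 and 554; without small-RNA entries they were 1703 and 2823, and 148 and 372. Cholesterol synthesis fell in 22 of 23 members with hairpin 1 and 22 with hairpin 2 (22 and 23 when adjusted over the list alone), with medians of -0.86 and -0.55, and 22 fell with both. YAP-TEAD targets fell in 17 of 18 members with hairpin 1 (18 when adjusted over the list alone), and with hairpin 2 in 4 with 1 rising (5 and 1 when adjusted over the list alone). With hairpin 2, Nt5e (-0.83), F3 (-0.45), Ctgf (-0.30) and Ankrd1 (-0.25) fell and Ajuba (0.23) rose, the last not after median-ratio scaling or chromosome centring; Nt5e, Ctgf and Ajuba were named after their values were seen. In hypoxia and glycolysis 18 members rose with hairpin 1 and 12 with hairpin 2 (19 and 13 when adjusted over the list alone). With hairpin 2 this was 7 after median-ratio scaling and 6 after chromosome centring. Camera in limma called cholesterol synthesis for each hairpin (adjusted p = 1.67e-16 and 2.85e-31, and adjusted p = 0.0494 and 0.0189 with an estimated correlation). With hairpin 1 camera also called YAP-TEAD targets, hypoxia and glycolysis, RAS-MAPK output and mesenchymal genes (adjusted p = 1.66e-11, 0.00142, 0.00168 and 0.0110). With hairpin 2 it also called TGF-beta response, hypoxia and glycolysis and S phase (adjusted p = 0.000615, 0.00185 and 0.00538). These other calls were all lost with an estimated correlation.

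The calls for hairpin 2 rested on few libraries. The count was 6 without hairpin 2 replicate 1, 9 without hairpin 2 replicate 2, 97 without either hairpin 1 library and 2653 without shNT replicate 2; at unadjusted p under 0.05 limma gave 2341 and 2210 in the fits without a hairpin 2 library. The hairpin 1 count was 3749 without hairpin 1 replicate 1 and 3765 without hairpin 1 replicate 2. For hairpin 2, limma called 0 of 23 cholesterol genes without either hairpin 2 library and 11 without either hairpin 1 library, while 23 were lower and 22 had an unadjusted p under 0.05 in each of these fits. In each of the 6 fits that left out a library, camera at the preset correlation gave that list a lower direction for hairpin 2. The estimated correlation was not run in those fits. Of the hypoxia and glycolysis genes, limma called 0 without either hairpin 2 library and 1 without either hairpin 1 library, with 13 and 14 higher at unadjusted p under 0.05. Of the YAP-TEAD targets, 0 were called without either hairpin 2 library, with 4 and 5 lower at unadjusted p under 0.05, and 2 were lower without either hairpin 1 library. With only shNT and hairpin 2 in the fit, limma called 98 genes, among them 11 of cholesterol synthesis, 1 of hypoxia and glycolysis and 2 YAP-TEAD targets.

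**Figure D2:**
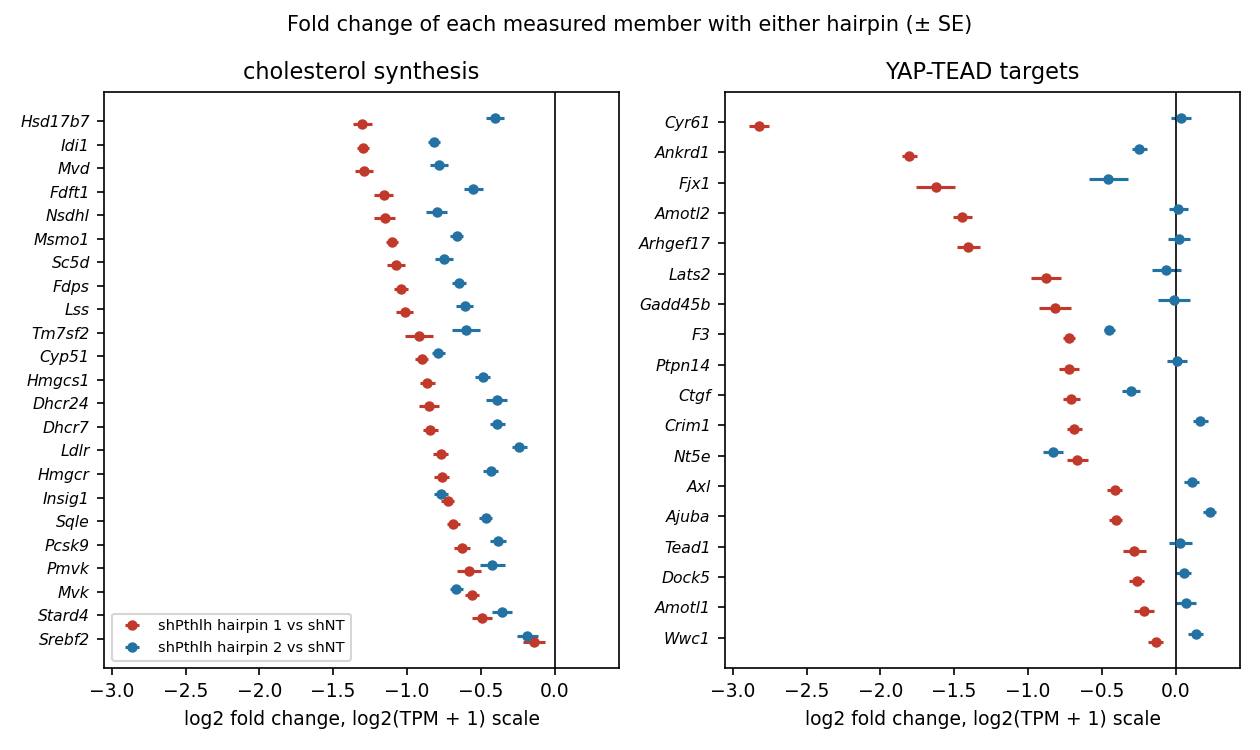
Log2 fold change on the log2(TPM + 1) scale (horizontal axis) of each tested gene of cholesterol synthesis (left) and of the YAP-TEAD targets (right), for hairpin 1 and hairpin 2 against shNT; points are estimates from 2 libraries per group and bars are SE. The 23 cholesterol genes lie below 0 with both hairpins, whereas Cyr61 is at -2.82 with hairpin 1 and 0.04 with hairpin 2; median-ratio scaling moved the hairpin 2 median of the YAP-TEAD targets from 0.02 to -0.07.

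The overlap of both hairpins was set against chance. Higher with both were 558 genes, against 245 for independent lists, and lower with both were 259, against 63.0. Simulated groups with no changed gene, which shared their simulated shNT libraries, gave 0 and 0.05 such genes on average over 20 simulations. With no gene changed hardly any gene is called for either hairpin. These values therefore do not give the overlap that shared controls would add among the real calls. In all, 74 genes were called in opposite directions. After median-ratio scaling the shared counts were 173, against 55.4, and 421, against 134. The fold changes correlated across genes at r = 0.450 and rho = 0.468, and the simulated unchanged groups gave 0.498 and 0.461. The same-sign share was 69.9% against 66.7% simulated. The covariance was 0.0658 against 0.0125 simulated, a difference of 0.0533. With a different shNT library for each hairpin r was 0.250 and 0.210. The controls cannot be split into sets of 2 libraries, so part of the excess may come from the shared controls.

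The direct comparison of the hairpins gave large differences. YAP-TEAD targets were higher with hairpin 2 in 17 of 18 members (17 when adjusted over the list alone, median 0.69), and cholesterol genes in 17 of 23 (17 when adjusted over the list alone, median 0.35). Palm3, a paralemmin, was at 32.0 TPM with hairpin 2 and 3.14 with hairpin 1, and Flnc, a filamin, at 24.1 and 2.43. Cdx2 differed by -4.60 ± 0.10 (log2, SE), Igfbp5 by -4.31 ± 0.10, Ppp1r1b, a phosphatase regulator, by -4.11 ± 0.09, Twist2 by -3.90 ± 0.20 and Ugt1a7c by -3.84 ± 0.06. In total 4626 genes differed in limma, 2297 higher with hairpin 2 and 2329 lower. Mir7655 and Mir8115 were higher with hairpin 2 and listed at 0 with hairpin 1. Their calls were lost without hairpin 1 replicate 1 (limma adjusted p = 0.0638 and 0.0706), hairpin 1 replicate 2 (0.0641 and 0.0709) or hairpin 2 replicate 2 (0.0644 and 0.0764).

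Of the other lists, RAS-MAPK output had 10 of 21 members higher with hairpin 2 and 3 lower (10 and 4 when adjusted over the list alone). G2-M phase had 14 of 30 higher and 3 lower (15 and 3 when adjusted over the list alone, 10 and 1 after chromosome centring), and hypoxia and glycolysis 2 of 26 higher and 12 lower (2 and 13 when adjusted over the list alone). Camera in limma called these 3 lists (adjusted p = 0.0206, 0.0116 and 0.0206) as well as cholesterol synthesis and YAP-TEAD targets (5.50e-06 and 1.96e-08). The 5 calls were lost at adjusted p = 0.274, 0.274, 0.534, 0.186 and 0.186 with an estimated correlation. The count of differing genes was 2525 without hairpin 1 replicate 1, 2439 without hairpin 1 replicate 2, 2374 without hairpin 2 replicate 1 and 2488 without hairpin 2 replicate 2. Of hypoxia and glycolysis genes 7 were lower without hairpin 1 replicate 2, hairpin 2 replicate 1 or hairpin 2 replicate 2. In G2-M phase 9 were higher without hairpin 1 replicate 2, 9 without hairpin 2 replicate 1 and 8 without hairpin 2 replicate 2.

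Genes of some chromosomes moved together, a pattern examined after seeing the data. Relative to the median of all genes, the median gene of chromosome 2 was at -0.37 (log2) with hairpin 1, that of chromosome 16 at -0.31, chromosome 9 at -0.24 and chromosome 19 at -0.17. With hairpin 2 chromosome 9 was at -0.18, and the other chromosomes lay between -0.08 and 0.08. Chromosome 9 held 5.58% of tested genes and 22.2% of those lower with hairpin 2. On chromosomes 2 and 16, 85.9% and 86.2% of tested genes lay below the median with hairpin 1. With hairpin 1, 22 of 22 windows of 40 genes on chromosome 2 and 8 of 8 on chromosome 16 were below it. With hairpin 2 these were 21 of 22 and 7 of 8, and 70.0% and 57.2% of the tested genes lay below it. The camera calls of limma for chromosomes 2 and 16 with hairpin 1 were lost at adjusted p = 0.0511 and 0.0836 with an estimated correlation. Chromosomes 2, 16 and 19 held 14.6% of tested genes and 37.0% of those lower with hairpin 1, among them Thbs1, Sulf2, Ankrd1 and Dusp5. Of the 23 cholesterol genes 3 lay on chromosomes 2, 9, 16 or 19.

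**Figure D3:**
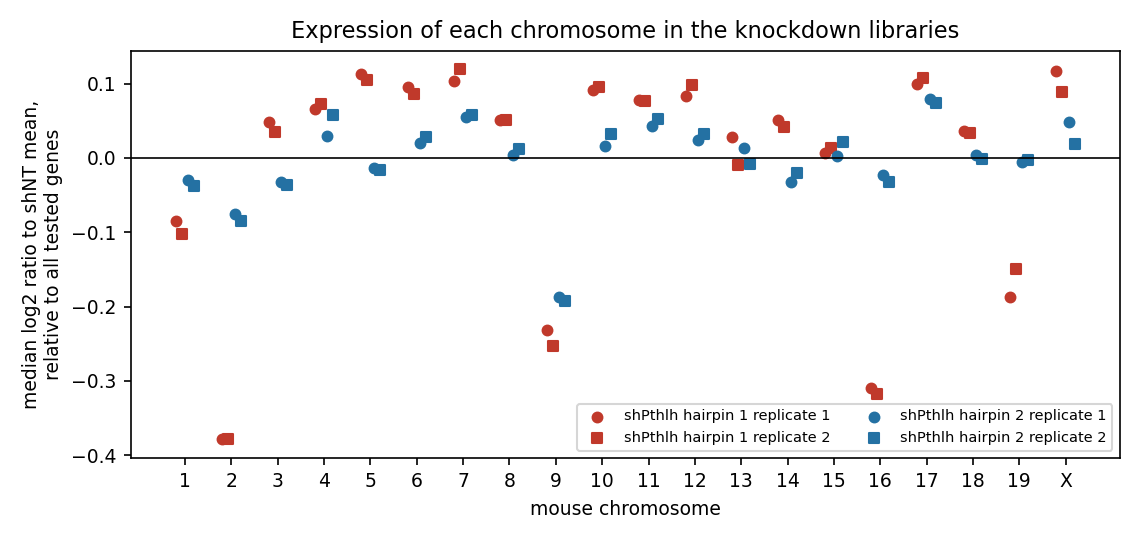
Median log2 ratio to the shNT mean of the tested genes on each mouse chromosome, relative to all tested genes (vertical axis), in each of the 4 knockdown libraries; points are libraries. The hairpin 1 libraries lie at -0.38 on chromosome 2, and both hairpins lie below 0 on chromosome 9.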

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

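The tests of chromosomes 2 and 16, of another cell type, of the scaling of TPM and of the hairpin 2 calls kept without the length trend were chosen after the result was seen, and the corrections for chromosomes and transcript length were added after seeing the data.

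These results differed between the hairpins in a direct test (limma, hairpin 2 minus hairpin 1). In all, 4626 genes differed. Median differences (log2) were 0.69 for YAP-TEAD targets, 0.35 for cholesterol synthesis, 0.18 for RAS-MAPK output, 0.17 for G2-M phase and -0.16 for hypoxia and glycolysis. The camera calls of these lists in limma were lost at adjusted p = 0.186, 0.186, 0.274, 0.274 and 0.534 with an estimated correlation.

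Of the largest changes with knockdown, the log2 difference was -4.60 for Cdx2, -4.31 for Igfbp5, -3.84 for Ugt1a7c, -2.02 for Prl2c3, -1.19 for Tff2, 1.23 for Mir23a and 1.78 for Mir421. It was 2.51 for Timp3, 2.38 for Thbs1, 2.04 for Hs6st2, 1.92 for Mmp13, 1.51 for Dbn1, 1.42 for Sulf2 and 1.42 for Fermt2. Of the largest differences between hairpins, it was 2.99 for Palm3, 2.88 for Flnc, 2.86 for Cyr61, -4.11 for Ppp1r1b and -3.90 for Twist2. Mir1b, Mir7655 and Mir8115 were at 3.18, 8.99 and 6.01 TPM with hairpin 2 and listed at 0 with hairpin 1, and Mir1956 was at 5.30 TPM with hairpin 1 and listed at 0 with hairpin 2.

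Among members of the signalling and mesenchymal lists, the log2 difference was 0.41 for Stc1, 1.03 for Dusp1, 1.44 for Dusp5, 1.29 for Epha4, 0.77 for Hbegf, -0.43 for Spry1, 0.73 for Pmepa1, -0.70 for Id3, -0.48 for Id2, 0.41 for Skil, 1.26 for Sparc and 0.37 for Cald1. It was 1.56 for Ankrd1, 0.28 for F3 and 1.46 for Amotl2 among YAP-TEAD targets, and 0.48 for Idi1, 0.44 for Msmo1 and 0.39 for Fdps among cholesterol genes. Among epithelial and subtype genes it was 2.48 for Cdh3, -1.18 for Krt19, -0.95 for Elf3, -0.42 for Crb3, -2.62 for Lgals4, 0.72 for Ctse, -1.13 for Foxa1, 0.98 for Lamb3, 0.62 for Scel and -0.60 for Sprr1b.

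In the remaining lists the log2 difference was -0.21 for Mcm7, 0.42 for Kif23, 2.70 for Igfbp3, 2.19 for Plk2, 1.40 for Cdkn2b, 1.83 for Cdkn2a, -0.72 for H2-D1, -0.91 for Oasl1, -0.64 for Cxcl5, -0.69 for Cxcl3, 1.82 for Ptgs2, 0.88 for Inhba, 0.80 for Gdf11 and -0.50 for Tnfsf12. It was -0.68 for Pfkl, -2.06 for Pfkp, -0.38 for Hk1, 0.53 for Hspa5, 0.85 for Atf3 and -0.92 for Xbp1. Among markers of other cells it was -1.20 for Mrc1, -0.49 for Apoe, -0.33 for Cd14, -0.66 for Flt1 and 1.08 for Col5a1.

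The hairpins differed in 4626 genes. On chromosomes 2 and 16, 84.8% of tested genes were higher with hairpin 2 relative to all genes; they were chosen for their shift, so this share restates it, and a difference in copy number stays open. After each chromosome was centred 4061 genes were called, and 3490 of the 4626 stayed called in the same direction. This argues against the common shift of the genes on each chromosome as the cause of the whole difference. Centring leaves any effect of such a shift on genes elsewhere in place, so that effect was not tested. Of genes above 5 TPM in shNT, 33 were lower by more than 2 (log2) with hairpin 1. Another cell type added to the hairpin 1 libraries, with no more RNA than the tumour cells, would lower no gene by more than 1. The 33 genes argue against that case. They do not cover another cell type in the shNT libraries that was absent with hairpin 1. A difference between the 2 parental clones, to which no label ties a hairpin, and off-target effects were not tested and stay open, as does the depth of knockdown, where Pthlh differed by 0.13 (log2) between hairpins (95% interval -0.18 to 0.44; limma adjusted p = 0.533).

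Cholesterol synthesis genes were lower with both hairpins. After median-ratio scaling 23 of 23 members were lower, with the length trend removed 23, and after centring each chromosome 23. Each correction also moved the median of all genes from 0.10 (log2) to 0.01 or less, which lowers the members too, so these counts alone decide nothing. The list test compares members with the other genes. It kept its call in these settings (camera in limma, preset correlation, adjusted p = 3.92e-17, 3.22e-17 and 3.16e-19), which argues against each of these as the whole cause. A response to Pthlh loss stays open as a hypothesis, and so does any feature shared by both hairpin lines and absent from shNT, such as their handling. The 2 shNT libraries serve both comparisons, so a peculiarity of shNT could give the same pattern.

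For hairpin 2, 1112 genes were called. With the length trend removed the count was 1013 and without shNT replicate 1 it was 964 (rho with length = -0.335 across genes for shNT replicate 2 minus 1), but in each fit only 682 of the 1112 stayed called in the same direction, so the counts alone decide nothing. The 682 argue against the length trend as the cause of all the calls, and for the others it stays open. The share of calls that were higher was 68.8% in deposited TPM and 30.6% after median-ratio scaling, which centres the genes and so moves this share by itself. Without small-RNA entries, a rescaling that does not centre the genes, the share was 28.5%. The excess of higher genes thus depended on the scaling of TPM, and which scaling is right was not tested. Whether hairpin 2 had a biological effect on these genes was not tested.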

How the results depend on the processing

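Removal of length and GC trends, chromosome centring, omission of small-RNA entries and separate controls were alternatives chosen after seeing the data. Where an omitted library left 1 library in a group, that library was assumed to vary like the others. Depth is unknown, which limits genes of low TPM such as Pthlh most.

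The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated across genes at 0.0211, 0.0152 and -0.0439. With the replicate block the hairpin 2 count was 276. Among these, 16 of 23 cholesterol synthesis genes were lower, against 22 without the block. There, 6 of 26 hypoxia and glycolysis genes were higher and 2 of 18 YAP-TEAD targets lower. The knockdown, hairpin 1 and between-hairpin counts of 4215, 5585 and 4200 stayed within 1.5 times. With only the groups compared, the knockdown count was 1 and the hairpin 2 count 98; the knockdown fit put the hairpin difference into the spread. In that fit the Pthlh level change stayed at -0.76 with a limma adjusted p of 0.0980, over a range of 0.00714 to 0.0980 for 17 alternatives.

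The knockdown count was 3032 after chromosome centring and 2907 without small-RNA entries. The hairpin 2 count was 585 without the filter, where 18323 genes were tested, 729 with quantile normalization, 552 after chromosome centring and 520 without small-RNA entries; the cause was not tested. The share of knockdown calls that were higher was 69.2%, and 44.7% after median-ratio scaling, 46.1% after quantile normalization, 45.5% after chromosome centring, 47.05% with the length trend removed and 33.1% without small-RNA entries. For hairpin 1 it was 63.85%, and 48.35%, 49.0%, 48.0%, 49.5% and 37.6% in the same order, and for hairpin 2 it was 68.8%, and 30.6%, 32.4%, 33.7%, 34.1% and 28.5%.

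Leaving out each library gave 2727 to 4893 genes for knockdown, 3749 to 6181 for hairpin 1, 6 to 2653 for hairpin 2 and 2374 to 5677 between hairpins. It gave -0.84 to -0.67 for the Pthlh level, 0.406 to 0.559 for the hairpin agreement and 8 to 9 called lists in the gene list tests. With an estimated correlation 1 list was called in place of 8.

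The hairpin agreement of 0.450 was 0.457 with a pseudocount of 0.1, 0.486 with a mean TPM of at least 5, 0.460 after median-ratio scaling, 0.440 with the length trend removed, 0.430 after chromosome centring, 0.469 without small-RNA entries, and 0.250 and 0.210 with separate controls; the cause was not tested.

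Of 90 named genes, 9 kept their side of the threshold in the fits of only the groups compared, and 81 were no longer called. Genes named for a difference between hairpins were fitted there without shNT, so the hairpins were not pooled for them. With the hairpins pooled the 1 gene called was Itga2, which the rule for named genes did not take. Median-ratio scaling and quantile normalization each ended 1 call, and leaving out a library changed 5 to 11 of the 90. Cd14, uncalled at -0.01, was reversed without shNT replicate 2 (0.0249) and without hairpin 1 replicate 1 (0.0069), over a range of -0.0461 to 0.0249 for the omission of each library; the cause was not tested.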

Other observations

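The lists of fatty acid synthesis, LXR targets, intestinal differentiation and retinoid genes, 4 in all, were written after the data were seen. The intestinal and LXR tests were set in their present form after their results were seen.

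Most fatty acid synthesis genes fell with hairpin 1 (12 of 15 tested members, limma) and 8 fell with hairpin 2, and no list test was run. In the knockdown comparison 12 fell and 0 rose in limma, and 13 fell after chromosome centring; with hairpin 1 centring left 10 lower and 1 higher, and with hairpin 2 it left 9 lower. Of the 15, 8 lay on chromosomes 2, 9 or 19, which were shifted with hairpin 1. The list had medians of -0.58 with hairpin 1 and -0.34 with hairpin 2 (log2). The desaturases Scd1 and Scd2 fell by 0.70 ± 0.04 and fell by 0.76 ± 0.05 (log2, SE), from 135 TPM to 82.8 and 83.1 and from 608 TPM to 341 and 379 with hairpins 1 and 2. The elongase Elovl6 fell by 0.60 ± 0.05. Fasn, fatty acid synthase, fell by 0.55 ± 0.06, without a call for hairpin 2 (limma adjusted p = 0.125), and was at 28.3 TPM with hairpin 1 and 47.9 TPM with hairpin 2 (limma adjusted p = 0.00108 for the difference). Srebf1 (-0.07), Me1 (-0.09) and Gpam (0.10) did not pass.

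Among retinoid genes 4 of 11 tested members rose and 2 fell, and 3 rose and 2 fell after median-ratio scaling. The values of Aldh1a1, Aldh1a3 and Dhrs3 had been seen before the list was written. Aldh1a1, a retinaldehyde dehydrogenase, rose by 1.61 ± 0.13 (log2, SE). Dhrs3 rose by 1.60 ± 0.07 and Aldh1a3 by 0.98 ± 0.11. Both were without a call for hairpin 2 (limma adjusted p = 0.248 and 0.0867), where Aldh1a3 was at -0.44. Rbp4 rose by 0.23 ± 0.06, without a call for hairpin 1 (limma adjusted p = 0.205). Stra6 fell by 0.75 ± 0.08 and Rdh10 fell by 0.24 ± 0.05, both without a call for hairpin 2 (limma adjusted p = 0.0604 and 0.431), where Rdh10 was at 0.07. The Rbp4 call was lost without hairpin 1 replicate 1 (limma adjusted p = 0.0974), hairpin 1 replicate 2 (0.0805), hairpin 2 replicate 1 (0.0808) or hairpin 2 replicate 2 (0.0953). The Rdh10 call was lost without hairpin 1 replicate 1 (limma adjusted p = 0.0550), hairpin 1 replicate 2 (0.0647) or hairpin 2 replicate 1 (0.0611).

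A hypothesis for the fall of the cholesterol genes is a lower output of the sterol-regulated SREBP programme, which also drives fatty acid synthesis genes. It would lower those too, and 13 of 15 were called lower after median-ratio scaling, which is consistent with it. An excess of cellular sterol, which would raise LXR targets, may lie upstream; 0 of 3 tested LXR targets were called higher after median-ratio scaling. Nr1h3 was called lower in that setting (-0.44, limma adjusted p = 0.0264), and Nr1h2 and Lpcat3 were not called. With only Nr1h2, Nr1h3 and Lpcat3 tested, of which Nr1h2 and Nr1h3 encode the LXR receptors themselves, that result decides nothing.

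A second hypothesis is an intestinal differentiation programme that rises with Cdx2 under hairpin 1. Of 7 tested intestinal genes other than Cdx2, Cdh17, Lgals4 and Tmigd1, whose values were seen earlier, 4 were called higher with hairpin 1 after median-ratio scaling. The 4 were Vil1, Krt20, Tm4sf4 and Fabp1. Of all 11549 tested genes 2623 were higher in that setting. Krt20 and Tff3 are also in the preset classical subtype list, so their calls entered a result above. Fabp1 passed the expression filter only through hairpin libraries, so it could only be called higher. These few genes go with the hypothesis but do not decide it. Fabp2 (-0.28), Tff3 (0.32) and Apoa1 (0.54) were not called in that setting (limma adjusted p = 0.0511, 0.142 and 0.119). Of 20 listed intestinal genes only 11 were tested. The remainder were absent or below the expression filter and do not enter this count, which limits it. Fabp1 was listed at 0 in shNT and was at 1.97 TPM with hairpin 1 but also 1.83 TPM with hairpin 2, where Cdx2 was at 1.01 TPM, which goes against a link to the level of Cdx2 for this gene. Tm4sf4 rose by 0.94 ± 0.07 (log2, SE) with hairpin 1 and fell by 0.79 ± 0.07 with hairpin 2. A difference between parental clones stays open and was not tested.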
